A study of Cavia porcellus with 18 samples.

How the data were processed

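Hippocampi of 3 wild type male guinea pigs (Cavia porcellus) of 12 weeks were used for 18 libraries. Per the labels, chromatin fixed with formaldehyde was sonicated and precipitated with an antibody against H3K4me1, a histone mark of enhancers and of the flanks of promoters, or against RNA polymerase II PS5 (Pol II PS5, the form phosphorylated on serine 5 that is found at initiation). H3K4me1 ChIP-seq, H3K4me1 ChIP followed by bisulfite sequencing (ChIP-bisulfite) and Pol II PS5 ChIP-seq had 3 libraries each, 1 per animal. Reduced representation bisulfite sequencing (RRBS), in which DNA cut with the restriction enzymes MspI and ApeKI is treated with bisulfite, had 6 libraries from the 3 animals, read at 50 and at 100 bases. A further 3 RRBS libraries were digestion controls without bisulfite and were not analysed here.

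The submitters' processing notes name Bowtie2 2.2.3, SAMtools 1.1, MACS2 and HOMER 4.6 for the ChIP-seq libraries, Bismark 0.12.5, SAMtools 1.1, methylKit, MACS2 and HOMER for the ChIP-bisulfite libraries, and BSMAP 2.74, SAMtools 1.1 and methylKit for RRBS. The notes give no role or order for these tools. The genome build was not given in the sources used here. Positions are therefore printed as the files give them, on their scaffold names, and whether the first base of a scaffold counts as 0 or 1 was not stated.

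The deposited values hold 1 value per assay for all animals together. A spread between animals could not be computed, and no test below compares animals. Methylation levels of single CG sites were deposited as whole percent, per the file headers, for the sites measured in both bisulfite assays. The number of reads per C position was given by the authors as counts for RRBS, for positions with at least 10 reads. A deposited table of averages gives for each of 99978 H3K4me1 peaks the methylation level in percent, the number of C positions and the reads over them in each assay. Its ChIP-bisulfite reads are whole counts, while its deposited RRBS reads were treated as estimated counts, since 975 of 198160 lines held a number that was not exactly whole. In 98.7% of the peaks these reads equalled the sum of the RRBS counts per position. Deposited H3K4me1 peaks and Pol II PS5 peaks each carry the authors' score, which was used only to rank or filter peaks within its list. The H3K4me1 scores lie on 2 scales in 1 column. A low scale of 1.27 to 14.8 held 177756 peaks and a high scale, with multiples of 0.5 from 42 upwards, held 149926 peaks. The table of CG sites also carries a Pol II PS5 score per transcript, deposited by the authors, which was the same for all sites of each of the 20111 transcripts.

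The site table had 241970 lines, with a site repeated for each transcript it was listed with. Each of the 167387 sites was counted once, with the transcript whose start site was nearest and the highest Pol II score of its transcripts. Listed distances ran from -10001 bases upstream of a transcription start site to positions inside and beyond long genes. The authors' list of differentially methylated sites was compared with the levels. Membership of the list matched, for all 167387 sites, a rule of at most 30% in one assay and at least 70% in the other. No q-value was given in it, so the counts below are the authors' and carry no test.

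The table of averages held 99978 peaks, of which 98182 were listed once with the nearest start site called Active and once with the nearest called Inactive. The definition of these words was not given in the sources used here. RRBS columns were identical in both entries of each of these 98182 peaks, but the ChIP-bisulfite columns were identical in only 18.5% of them. A displacement of the ChIP-bisulfite columns by a whole number of lines, from -6 to 6, was fitted along the Active and the Inactive part of the table. The fit minimised the distance between the peak level and the mean level of the peak's sites in the site table, with a penalty on each change of displacement. Lines were displaced by 1 or 2 over 125634 of 198160 lines (63.4%). After the move 98113 peaks (99.9%) had identical entries, although the fit had not used the pairing of entries. Over the Active entries of these peaks, Spearman's rho between peak level and mean site level rose from 0.234 to 0.611, against 0.721 for RRBS. Peak results use these 98113 peaks with the lines moved, and the deposited order was run as an alternative. On simulated data with 20000 lines the procedure gave 99.7% of the lines their true displacement and left 100% of the lines in place where none was displaced.

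Differences between groups of sites or peaks were tested with two-sided permutation tests of 100000 resamples, in which 1e-05 is the smallest p they can give. The unit was the H3K4me1 peak, and sites were averaged within it first. In comparisons of sites by Pol II, a peak with sites in both groups gave a mean to each, and these means were not paired. Peaks share animals, reads and chromosomes, so these p-values describe the pooled libraries and say nothing of the spread between animals. Standard errors and 95% intervals of means came from 1000 bootstrap resamples of scaffolds and do not cover animals either. Shares of sites were compared with Fisher's exact test, two-sided, and shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Both take sites as independent, although sites share peaks and reads, so these p-values may be too small and the intervals too narrow. Benjamini-Hochberg adjustment was made within each family of tests. Overlap of peaks was counted from 1 base and compared with 100 random placements of the Pol II peaks within their scaffolds. Peak averages were used where each assay had at least 3 C positions in the peak. CG density is the number of such positions in the genome, as the authors' table gives it, per 1000 bases of peak. With no difference simulated over 2000 peaks, 4.5% of permutation p-values were under 0.05, and with a difference of 8 points 100% were. Scaffold bootstrap intervals held the true mean in 91.7% of simulated sets of 10000 sites. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

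Regions were named by a rule fixed before the data were examined, which asked for the 10 with the largest difference in each direction among those called and the 10 highest-scoring peaks of each kind. A region was taken as an H3K4me1 peak with at least 3 sites in both assays, at least 1 of them on the authors' list, ranked by the mean difference. That reading of the rule was made once the files were seen to hold no q-value. Genes appear in the files by identifier only. None of the 19244 identifiers matched the available RefSeq gene table (assembly mCavPor4.1), so no symbols are given, and the 12 gene lists fixed in advance could not be run. Alternatives covered the read minimum, the difference and class limits, stricter or wider peaks, the overlap rule and the number of C positions per peak. The planned relation between H3K4me1 score and methylation is not reported here.

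Depth set the precision as follows. RRBS covered 5053261 C positions with a median of 17 reads. Reads per site were not given for ChIP-bisulfite, but over the peaks with averages its median was 16 reads per C position, against 20 for RRBS. A level from 16 reads moves in steps of several points, so single sites are imprecise and averages over many sites are not limited by counting.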

Results

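DNA methylation in H3K4me1 peaks was measured in the hippocampus of 3 guinea pigs by 2 bisulfite assays. RRBS reads the methylation of DNA near restriction sites regardless of chromatin, and ChIP-bisulfite reads it on DNA that was precipitated with H3K4me1. H3K4me1 ChIP-seq gave the H3K4me1 peaks, in which enhancers and promoter flanks were not separated, and Pol II PS5 ChIP-seq gave the Pol II PS5 peaks. All deposited values pooled the 3 animals, so errors below are across scaffolds, sites or peaks and not across animals. The H3K4me1 list held 327682 peaks with a median width of 1785 bases, which covered 870.1 Mb, or 32.0% of the span of the scaffolds. The Pol II PS5 list held 67423 peaks with a median width of 259 bases that covered 0.823% of the span. RRBS covered 5053261 C positions with a sum of 131062338 reads. Both assays measured 167387 CG sites, all inside 45331 H3K4me1 peaks, and the RRBS level of these sites rested on a median of 17 reads.

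The first comparison asked how methylation on H3K4me1-bound DNA differed from that of the same CG sites in the whole tissue. The assays also differed in how DNA was cut, in the processing tools named and in the number of libraries. All shared sites lay in H3K4me1 peaks, so a gap due to H3K4me1 binding cannot be told apart from an offset between the protocols. The mean level was 45.1% in ChIP-bisulfite (scaffold SE 0.402, 95% interval 44.2 to 45.8) and 53.9% in RRBS (SE 0.453, 53.0 to 54.7). ChIP-bisulfite was lower by a mean of -8.83 percentage points (95% interval -9.09 to -8.55). The median site differed by 0 points, since 42.1% of the sites were lower in ChIP-bisulfite, 30.9% were higher and 27.0% had equal values. Across sites the levels of both assays had a Spearman's rho of 0.595.

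ChIP-bisulfite placed more sites at the ends of the scale. Sites at or under 20% made up 47.4% of the sites in ChIP-bisulfite and 27.2% in RRBS, and sites at or over 80% made up 37.4% and 34.7%. Between these limits lay 15.2% of the sites in ChIP-bisulfite and 38.2% in RRBS. Levels of exactly 0 or 100 were listed for 66.6% of the sites in ChIP-bisulfite and for 36.7% in RRBS. Of the 63879 sites at intermediate level in RRBS, 45.9% were at or under 20% in ChIP-bisulfite, 33.8% were at or over 80% and 20.3% stayed between. Sites low in RRBS were low in ChIP-bisulfite in 85.2% of cases, while 66.1% of the sites high in RRBS were high and 19.4% were low. Reads per site were not given for ChIP-bisulfite, and few independent molecules at a site would also place levels at 0 or 100. Adjacent C positions were at least 40 points apart in 27.2% of pairs in ChIP-bisulfite and in 11.8% in RRBS. A split of H3K4me1-bound DNA into low and high states was therefore not shown.

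**Figure D1:**
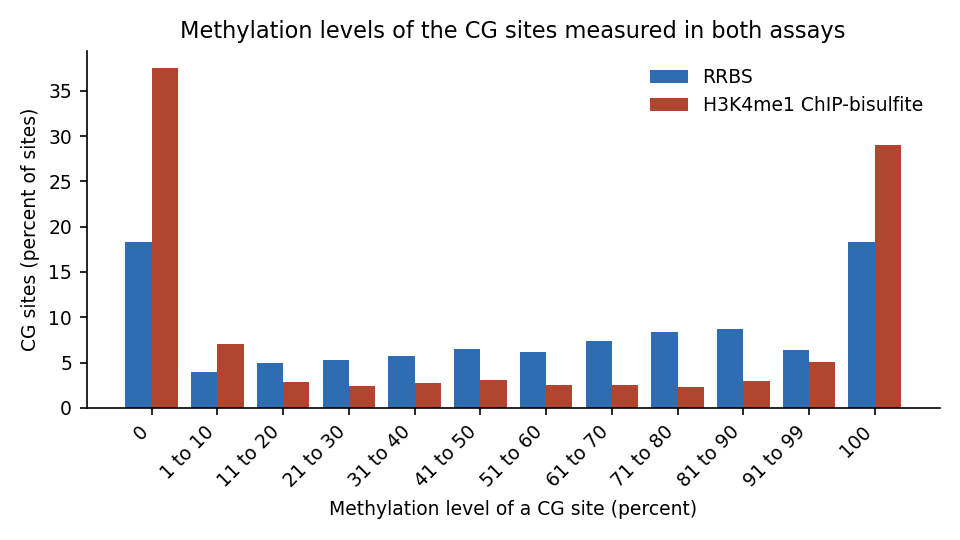
Share of the 167387 CG sites (vertical axis, percent of sites) in each band of methylation level (horizontal axis, percent), with blue bars for RRBS and red bars for H3K4me1 ChIP-bisulfite, each pooled over the animals. The red bars stand at 37.5% of the sites for a level of 0 and at 29.0% for a level of 100, against 18.3% at either end in RRBS.

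Methylation dipped around transcription start sites in both assays, and the gap between the assays in percentage points was narrow there. A lower RRBS level leaves less room for a fall, and the gap was not compared at equal RRBS level. From the start site to 1000 bases upstream, the mean level was 23.2% in ChIP-bisulfite (scaffold SE 0.823) and 27.2% in RRBS (SE 0.800) over 10692 sites, a difference of -3.98 points (95% interval -4.79 to -3.16). In the first 1000 bases downstream the levels were 25.7% and 29.2% over 12124 sites. Levels rose to 47.3% and 52.5% in the next 1000 bases. At 10000 to 50000 bases downstream they reached 51.4% in ChIP-bisulfite and 62.7% in RRBS over 39100 sites, with a difference of -11.3 points (95% interval -11.8 to -10.8). Farther upstream than 5000 bases the levels were 43.2% and 51.2%.

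**Figure D2:**
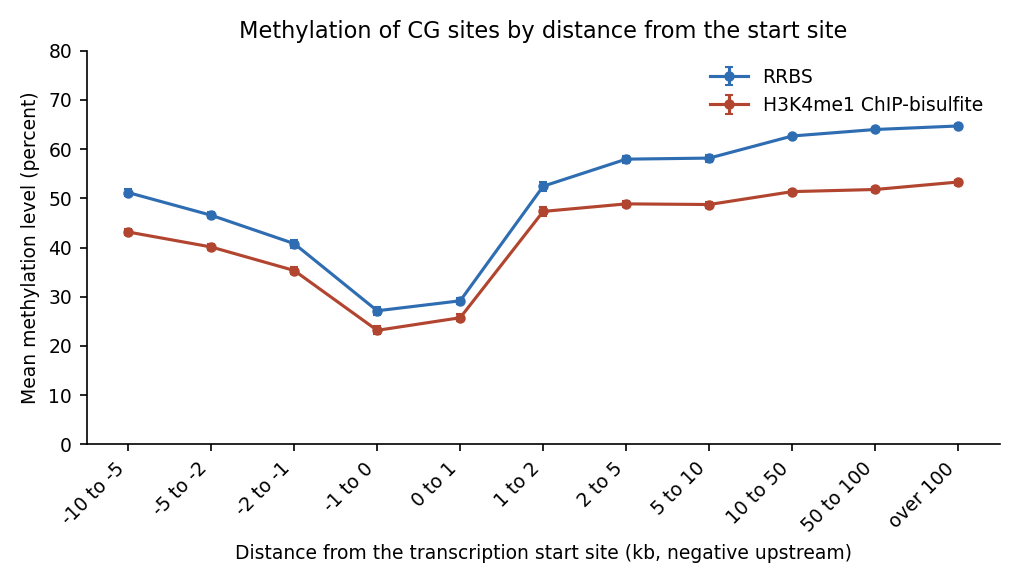
Mean methylation level of CG sites (vertical axis, percent) by distance from the nearest listed transcription start site (horizontal axis, kb, negative upstream) in RRBS (blue) and ChIP-bisulfite (red), with bars of 1 scaffold SE. Both lines have their lowest point in the 1000 bases upstream of the start site, at 27.2% and 23.2%.

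The authors listed 21980 CG sites as differentially methylated between the assays, 13.1% of the sites measured in both. Of these, 17077 (77.7%) were lower in ChIP-bisulfite, with a mean level of 5.62% against 87.9% in RRBS, and 4903 were higher, with 92.4% against 14.02%. With a difference of at least 10 points in place of the authors' list, 101038 sites differed and 60.1% of them were lower. Sites lower in ChIP-bisulfite lay in 11875 H3K4me1 peaks and sites higher in 4106, and 1445 peaks held sites of both directions. Within 1000 bases of a start site lay 5.996% of the lower sites (95% interval 5.64 to 6.36), 12.6% of the higher sites (11.7 to 13.5) and 14.6% of the sites not listed (14.4 to 14.7). The list's rule bears on these shares, since a lower site needs an RRBS level of at least 70% and a higher site one of at most 30%. Among the 71746 sites at 70% or more in RRBS, 22.9% of those within 1000 bases of a start site were listed lower and 23.9% of the others (odds ratio 0.948, Fisher's exact test, adjusted p = 0.20). Among the 54347 sites at 30% or less, 4.18% and 10.8% were listed higher (odds ratio 0.359, Fisher's exact test, adjusted p = 4.0e-146, 4 tests), with the RRBS level not matched further. Sites that share a peak were taken as independent in both tests.

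Among 18741 H3K4me1 peaks with at least 3 shared sites, 9159 held a listed site, and the mean difference was negative in 7103 of them and positive in 2039. All sites were lower in ChIP-bisulfite in 659 of these peaks and higher in 95. The largest falls were at scaffold_81 from 1585268 to 1591317, downstream of the start site of ENSCPOG00000005459 by 29187 bases, and at scaffold_82 from 1675455 to 1678619, downstream of that of ENSCPOG00000013336 by 76203 bases. In each, 3 sites were at 100% in RRBS and at 0% in ChIP-bisulfite, with median RRBS reads of 18 and 13, and the first of them also overlapped a Pol II PS5 peak. The other 8 of the 10 leading peaks had mean differences from -98.3 to -94 points over 3 or 4 sites. They lay on scaffold_10 (8667089 to 8669616), scaffold_41 (3165909 to 3170943), scaffold_110 (3481567 to 3486325), scaffold_2 (58472876 to 58479593), scaffold_131 (1229924 to 1232320), scaffold_25 (25571097 to 25574608), scaffold_29 (820384 to 822249) and scaffold_0 (4770823 to 4776741). In the other direction, the peak at scaffold_85 from 1448952 to 1455707, with ENSCPOG00000007981 as nearest start site at 22463 bases, averaged 6.33% in RRBS and 100% in ChIP-bisulfite (mean difference 93.7 points, SD 10.97 over 3 sites). The peak at scaffold_18 from 2026322 to 2032354, downstream of the start site of ENSCPOG00000002025 by 5280 bases, averaged 3.67% and 91% (87.3 points, SD 3.21 over 3 sites). The remaining 8 had mean differences of 70 to 85.3 points. They lay on scaffold_346 (86250 to 89638), scaffold_15 (21803383 to 21807043 and 26220765 to 26223382), scaffold_4 (6014364 to 6017738 and 43796998 to 43800763), scaffold_71 (7530733 to 7531186), scaffold_87 (4109064 to 4120532) and scaffold_7 (60465567 to 60471886). Each of these values rests on 3 or 4 sites and on pooled animals, and whether the positions are exonic or intronic was not given in the files.

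Averages over whole H3K4me1 peaks gave a wider gap between the assays than shared sites. Over 80445 peaks with at least 3 C positions in each assay, the mean level was 49.1% in ChIP-bisulfite (SD 24 across peaks) and 62.5% in RRBS (SD 23.1), with a mean difference of -13.4 points (95% interval -13.6 to -13.1). The positions averaged were those of each assay and not always the same. Level times reads came within 0.02 of a whole read number in 100% of peaks with under 200 ChIP-bisulfite reads. For RRBS, with under 200 RRBS reads, this held in 22.8% of peaks, so the averages may also have been weighted differently. Unlike single sites, most peaks were intermediate in both assays, with 76.6% of the peaks between 20% and 80% in ChIP-bisulfite and 67.9% in RRBS. An average over at least 3 positions tends to the middle of the scale, so averaging alone can give this contrast with single sites. Levels fell with CG density. In the decile of peaks with the fewest CG positions, at most 12.4 per 1000 bases, ChIP-bisulfite averaged 59.5% and RRBS 69.5%. In the decile with the most, at least 57.2 per 1000 bases, the averages were 25.9% and 39.8%. The gap between the assays lay between -10.1 and -15.2 points in all 10 deciles. The ChIP-bisulfite columns of the deposited table were displaced by 1 or 2 lines over 63.4% of its lines, and these values use the lines moved back.

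**Figure D3:**
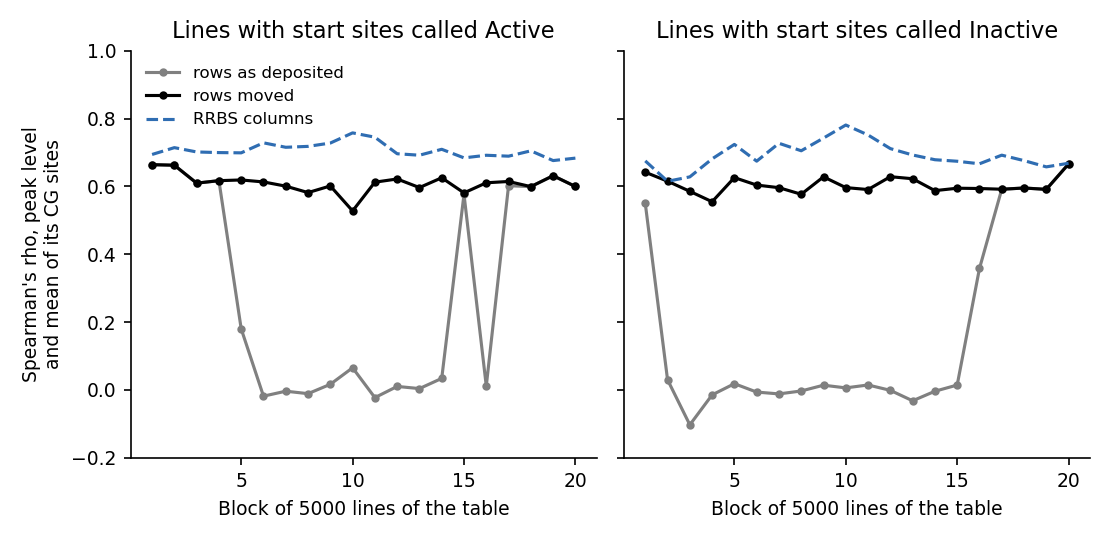
Spearman's rho (vertical axis) between the peak level in the deposited table of averages and the mean level of the peak's CG sites in the site table, by block of 5000 lines (horizontal axis), for lines with Active (left) and Inactive (right) start sites. Grey is the deposited order of the ChIP-bisulfite columns, black the order after the move and dashed blue the RRBS columns. Over the Active entries of the peaks listed with both kinds of start site, rho was 0.234, 0.611 and 0.721.

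For 98182 of its 99978 peaks the authors' table gives the distance to the nearest start site called Active and to the nearest called Inactive. Within 1000 bases of an Active start site, peaks averaged 29.3% in ChIP-bisulfite (scaffold SE 0.471) and 31.4% in RRBS (SE 0.743) over 1276 peaks. Within 1000 bases of an Inactive start site the averages were 33.2% (SE 0.471) and 43.1% (SE 0.562) over 3804 peaks. With the 573 peaks close to both kinds left out, RRBS was at 30.2% near Active and 44.9% near Inactive start sites, a difference of -14.6 points. ChIP-bisulfite was at 30.1% and 34.1%, a difference of -3.93 points. Both differences passed the permutation test over 703 and 3231 peaks (adjusted p = 1.5e-05 and 8e-05, 3 tests). The gap between the assays was -0.0976 points near Active and -10.8 points near Inactive start sites, and these gaps differed by 10.7 points (permutation test, adjusted p = 1.5e-05). Over the CG sites measured in both assays, a part of the averaged positions, RRBS was at 33.7% and 43.1% and ChIP-bisulfite at 32.4% and 37.6% in the same peaks. The gaps were then -1.31 points (SD 20.99) and -5.50 points (SD 26.5) and differed by 4.20 points (permutation p = 1e-04). Beyond 100000 bases from either kind, RRBS was at 64.3% and 66.0% and ChIP-bisulfite at 50.3% and 51.5%.

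**Figure D4:**
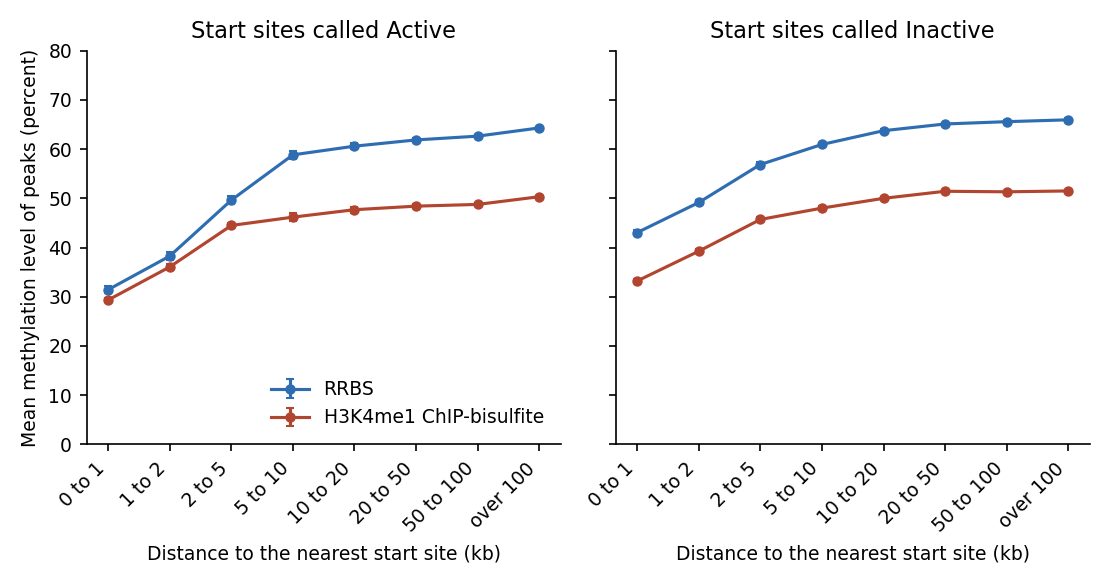
Mean methylation level of H3K4me1 peaks (vertical axis, percent) by distance to the nearest start site (horizontal axis, kb) called Active (left) or Inactive (right), in RRBS (blue) and ChIP-bisulfite (red), with bars of 1 scaffold SE. Within 1000 bases the lines stand at 31.4% and 29.3% near Active and at 43.1% and 33.2% near Inactive start sites.

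DNA under Pol II PS5 peaks was less methylated in both assays. The 3713 sites inside Pol II PS5 peaks had a mean level of 19.4% in ChIP-bisulfite (scaffold SE 1.23) and 23.6% in RRBS (SE 1.14), against 45.6% (SE 0.356) and 54.6% (SE 0.404) for the 163674 sites outside. For the test, sites were first averaged within each H3K4me1 peak, which gives peaks with few sites more weight. H3K4me1 peaks with sites both inside and outside entered both groups as separate units, and their pairing was not used. Means of these peak means were 24.2% inside (SD 37.2 over 1414 H3K4me1 peaks) and 52.1% outside (SD 38.0 over 45033 peaks) in ChIP-bisulfite, a difference of -27.9 points. In RRBS they were 28.4% and 61.6%, a difference of -33.2 points. The gap between the assays, averaged in the same way, was -4.22 points inside and -9.54 points outside, and it differed by 5.32 points. Each of these differences had an adjusted permutation p of 1.3e-05 (12 tests). Distance from start sites, CG density and, for the gap, the RRBS level were not held fixed in these site comparisons. A site low in RRBS can fall little further, so the smaller gap inside Pol II PS5 peaks may follow from the lower RRBS level there. Sites close to start sites were also low in methylation, so the part of the differences that goes with Pol II itself was not separated.

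The authors' Pol II score, 1 per transcript, gave another direction over all sites. Sites of transcripts with a score had a mean level of 46.4% in ChIP-bisulfite (scaffold SE 0.532) and those of transcripts without 42.5% (SE 0.357). Beyond 1000 bases from the start site the levels were 50.1% and 44.8%, but within 1000 bases they were 22.8% (SE 0.762) and 27.8% (SE 0.732). As means of peak means, the ChIP-bisulfite differences were 2.94 points over all sites, 4.03 points beyond 1000 bases and -9.38 points within 1000 bases (adjusted permutation p = 1.3e-05 each). In RRBS they were 3.29, 4.54 and -11.2 points (adjusted permutation p = 1.3e-05 each). The gap between the assays differed by -0.355, -0.518 and 1.87 points (adjusted permutation p = 0.27, 0.14 and 0.0086). Over all sites, peaks with sites of both kinds again entered both groups unpaired.

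Whole H3K4me1 peaks that overlapped a Pol II PS5 peak were also less methylated. The 9380 such peaks averaged 42.2% in ChIP-bisulfite (SD 22.2) and 51.2% in RRBS (SD 26.7), against 50.1% (SD 24.1) and 64.0% (SD 22.1) for 71065 peaks without, differences of -7.90 and -12.7 points (permutation p = 1e-05). Peaks within 2000 bases of a start site were at 31.7% with and 37.3% without Pol II in ChIP-bisulfite, and at 35.4% and 48.0% in RRBS. Farther than 20000 bases from any listed start site the levels were 48.4% and 51.8% in ChIP-bisulfite, and 60.2% and 66.4% in RRBS, over 3812 and 42922 peaks (adjusted permutation p = 1e-05 each, 9 tests). Peaks with Pol II lay closer to start sites and had more CG positions, and within strata of both the ChIP-bisulfite difference was -2.31 points and the RRBS difference -7.10 points (permutation p = 1e-05). With the table's lines in the deposited order the ChIP-bisulfite difference was -4.91 points.

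Of the sites listed lower in ChIP-bisulfite, 0.720% lay in Pol II PS5 peaks (123 sites, 95% interval 0.599 to 0.859), against 1.41% of the higher sites (69 sites, 1.097 to 1.78) and 2.42% of the sites not listed (2.34 to 2.502). The odds ratio was 0.508 for lower against higher sites (Fisher's exact test, adjusted p = 3.3e-05), 0.292 for lower sites against those not listed (adjusted p = 1.1e-58) and 0.575 for higher sites (adjusted p = 2.8e-06). Fisher's tests in this comparison took sites as independent, although sites share peaks. With 1 listed site per H3K4me1 peak, added after seeing the data, lower against higher sites gave 0.585 (Fisher's exact test, p = 0.012). These ratios are tied to the low RRBS level under Pol II PS5 peaks, where only 550 sites were at 70% or more and could be listed lower. Among all sites at 70% or more in RRBS, 22.4% of those inside and 23.8% of those outside Pol II PS5 peaks were listed lower (odds ratio 0.922, Fisher's exact test, adjusted p = 0.45). Among sites at 30% or less, 2.61% of 2647 sites inside and 9.35% of those outside were listed higher (odds ratio 0.259, Fisher's exact test, adjusted p = 8.1e-42, 4 tests), with the RRBS level not matched further. With all sites at least 40 points apart in place of the authors' list, lower and higher sites did not pass Fisher's exact test (odds ratio 0.844, p = 0.086). By the Pol II score per transcript, lower sites had a score slightly more often than higher ones, with an odds ratio of 1.096 (Fisher's exact test, adjusted p = 0.0081). The shares with a score were 67.3% of lower, 65.2% of higher and 66.0% of sites not listed, and the RRBS level was not matched.

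Pol II PS5 peaks lay in H3K4me1 peaks more often than random placement gives. Of 67423 Pol II PS5 peaks, 40977 (60.8%, 95% interval 60.4 to 61.1) overlapped an H3K4me1 peak, against a mean of 42.5% (SD 0.158) over 100 placements, of which the highest reached 42.9% (permutation p = 0.0099, the smallest these placements can give). Within 1000 bases of the 19847 listed start sites, 94.1% of 4113 Pol II PS5 peaks overlapped an H3K4me1 peak. Away from these start sites 37105 of 63310 (58.6%) did. Start sites were listed only for transcripts with a site in the site table, and all those sites lay in H3K4me1 peaks, so this contrast is partly set by how start sites were listed. In turn, 32020 H3K4me1 peaks (9.77%) held a Pol II PS5 peak.

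The 10 Pol II PS5 peaks with the highest scores were led by scaffold_1 from 68170505 to 68170697 (score 1149.38), 390993 bases from the nearest listed start site. Next came scaffold_1289 (3 to 1071, score 563), scaffold_9 (10234819 to 10235011, score 526.31), scaffold_0 (32313190 to 32313424, score 419.96), scaffold_13 (29785336 to 29785535, score 413.62) and the mitochondrial genome (1440 to 2465, score 408.67). Those on scaffold_90 (4 to 263), scaffold_36 (5172381 to 5172573), scaffold_17 (1139280 to 1139507) and scaffold_1506 (2082 to 2321) scored from 377.27 to 255.42. The highest H3K4me1 scores were at scaffold_71 from 314 to 1570 (score 3164), scaffold_351 from 43783 to 45044 (score 3014) and scaffold_927 from 40 to 10214 (score 2831), the last of which held a listed start site. The other 7 scored from 2490 to 1458.5 and lay on scaffold_219 (494012 to 495273), scaffold_1653 (11090 to 12157), scaffold_3061 (62 to 3769), scaffold_1434 (254 to 9636), scaffold_2372 (66 to 2438), scaffold_10 (4661230 to 4662732) and scaffold_7 (36486644 to 36488680).

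RRBS positions were more frequent in H3K4me1 peaks than the peaks' share of the sequence. Of the 5053261 positions, 2468787 (48.9%) lay inside H3K4me1 peaks, which covered 32.0% of the scaffold span, a ratio of 1.53. Median depth was 17 reads both inside and outside. Methylation levels of RRBS positions outside H3K4me1 peaks were not analysed here.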

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

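The comparison of start sites called Active and Inactive and its alternatives were chosen after seeing the data, while the test of read numbers at the highest-scoring Pol II PS5 peaks was set before its result was seen.

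The gap between ChIP-bisulfite and RRBS differed between H3K4me1 peaks near start sites called Active and peaks near those called Inactive. It was -0.0976 points (SD 23.4 over 703 peaks) near Active and -10.8 points (SD 22.6 over 3231 peaks) near Inactive start sites, a difference of 10.7 points (permutation test over peaks, p = 1e-05). Within quintiles of CG density the difference was 10.9 points, and with the table's lines in the deposited order it was 9.11 points. Over the CG sites measured in both assays it was 4.20 points (permutation p = 1e-04). The positions, their number and their weight within a peak can differ between these averages, and no test separated them. The RRBS level, which was lower near Active start sites, was not held fixed either.

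Signal outside the nuclear comparisons appeared on the mitochondrial genome, which carries no nucleosomes. It held 3 H3K4me1 peaks that covered 59.1% of its 16633 bases, with scores up to 122.5. It also held 8 Pol II PS5 peaks, with scores up to 408.67, the 6th highest of all Pol II PS5 peaks. RRBS had 41 positions there with a median of 64 reads. RRBS uses no antibody but is not a control of the precipitation, and no such control was analysed here.

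The 10 highest-scoring Pol II PS5 peaks were short or at scaffold ends in several cases, and few lay near a listed start site. Sequence with more copies in the cell than in the assembly, such as repeats or organelle sequence, may give such scores, and RRBS, which uses no antibody, would then also have more reads there. Over the 100 highest-scoring Pol II PS5 peaks with RRBS positions the median of the highest read number was 78, against 21 over the other 15044, a ratio of 3.71 (95% bootstrap interval 2.67 to 7). Read numbers above 100 occurred in 47% of the former and 5.20% of the latter. The ratio is on the side that extra copies predict, although its interval reaches below the bound of 3 set in advance. Pol II PS5 binding at these places was not excluded, and no biological explanation was tested.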

How the results depend on the processing

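No paired analysis was possible because the deposited values hold 1 value per assay for all animals together. For the same reason the planned runs that leave out an animal, block on the animal, use a q-value of 0.01 or drop the logit scale were not run, and the gene lists with their windows were not run because no identifier had a symbol. Of 44 alternatives, 23 kept the direction and the side of the threshold, which says nothing of their size. A further 17 kept their sign but moved beyond the margin set around the main value, 3 reversed and 1 was weaker. Among the 23 are those of the Pol II and overlap comparisons not named below. Those of the relation between H3K4me1 score and methylation, which is not reported here, are also among the 23. Where values moved, the cause was not tested unless given. Averages near transcription start sites and Pol II rest on many sites, while depth limits single sites.

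The mean assay difference of -8.83 points was -9.27 with at least 20 RRBS reads. With choices made after seeing the data it was -9.49 as a mean of peak means, -8.07 over all table lines, -13.4 from peak averages and -12.3 from these in the deposited order. The excess of sites at or under 20% in ChIP-bisulfite, 20.2 points, was 22.3 with limits of 10% and 90%, 17.4 with 30% and 70%, and 22.2 with at least 20 RRBS reads. The 21980 listed sites compare with 101038 sites at least 10 points apart, 80484 at least 20 points apart (added after seeing the data) and 48471 at least 40 points apart. At least 20 RRBS reads left 8168 of them because only 69050 sites entered, of which 11.8% were listed. The share of RRBS positions in H3K4me1 peaks was 41.2% with peaks at or above the median score, since fewer peaks entered, and 48.8% with at least 20 reads.

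The odds ratio of lying in a Pol II PS5 peak, lower against higher sites, was 0.844 (Fisher's exact test, p = 0.086) for sites at least 40 points apart. With the Pol II score per transcript, added after seeing the data, it turned to 1.096, and the difference at CG sites, over peak means, turned from -27.9 to 2.94 points. Over plain site means, also added, these differences were -26.2 and 3.92 points.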

Other observations

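The tests on displaced lines and those on adjacent positions both high or both low in RRBS were chosen after the result was seen, and the other tests on listed sites and adjacent positions were set before their results were seen.

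Away from start sites, Pol II PS5 peaks outside H3K4me1 peaks had scores like those inside. Of the 63310 Pol II PS5 peaks farther than 1000 bases from a listed start site, 26205 overlapped no H3K4me1 peak and had a median score of 3.43. The 37105 that overlapped one had a median score of 3.31, and the 4113 within 1000 bases of a start site had a median score of 5.08. Only genes of the site table gave start sites, so some of the distant peaks may lie at start sites not listed there; the overlap of all Pol II PS5 peaks, 56.8% when 50% of the shorter peak must be covered, does not depend on that list.

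In the table of peak averages, the ChIP-bisulfite columns differed between the entries of a peak in all but 18.5% of the peaks. A displacement of these columns against the coordinates is a candidate explanation, and a separate computation for Active and Inactive start sites is another. After the move fitted to the site table alone, 99.9% of the peaks had identical entries, which a separate computation would not give. The displaced lines formed a few long blocks, and RRBS columns were in place throughout. Whether the lines shifted before deposit or in a later step stays open, and no biological explanation was tested.

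Other sites of the same peak, at least 200 bases away, had a mean difference of -10.5 points for sites listed lower (12.9% of theirs, 95% interval 12.2 to 13.6) and -8.36 points for sites listed higher (-10.7% of theirs, -12.0 to -9.42), near the -8.83 points of all sites. Few independent molecules behind a ChIP-bisulfite level may give this for sites listed lower. For sites listed higher, the values fell on the side set in advance against a difference of the bound DNA over the whole peak. The other sites were not matched on RRBS level, however, and a site at 100% in RRBS cannot be higher in ChIP-bisulfite. The test therefore cannot decide whether such a difference covers the whole peak. Among adjacent C positions both at 70% or more in RRBS (2587 pairs), the second was listed lower in 31.7% of pairs with the first listed lower and in 11.6% of the others (odds ratio 3.56, Fisher's exact test with pairs taken as independent, p = 9.2e-27), so calls of adjacent positions were linked, and whether the same molecules link them stays open. Adjacent positions were at least 40 points apart in 27.2% of 10624 pairs in ChIP-bisulfite and in 11.8% in RRBS, and binomial sampling from the RRBS levels with the ChIP-bisulfite reads per position gave 14.9%. Over the 10536 pairs simulated, the observed share was 27.1%, and the SD of the simulated share over 100 simulations was 0.233. The simulated share was 55.0% of the observed one, between the bounds set in advance. This test cannot decide whether plain read sampling from the RRBS levels is the only source of such pairs. Depth was the average per position of a peak, set to at least 10 reads, since reads per site were not given. Lower or uneven depth at single sites would raise the simulated share. A smaller number of molecules was not shown by the simulation, and differences between strands, alleles or cells were not tested.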
